A study of Mus musculus with 7 samples.

How the data were processed

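The series measured messenger RNA levels in alveolar macrophages of wild-type (WT) and Cish-/- mice by RNA sequencing. Per the labels, the cells were sorted into TRIzol LS, total RNA was extracted with the Zymo Directzol kit, and libraries were made with Nextera XT, a method that does not mark the strand of the RNA. Reads of genes that overlap on opposite strands can therefore not be told apart. The deposited table holds raw read counts per gene symbol, produced with rsubread, an R package for aligning and counting reads. The submitters' notes name the mouse genome build mm10 and DESeq2. The annotation and the handling of reads that map to several places are not given in the sources used here, so counts of close paralogs and pseudogenes (such as Rpl29 and Gm8210, Lilr4b and Lilrb4a, Hspa1a and Hspa1b, the Ear genes and the H2 genes) may hold reads of one another.

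The table listed 27179 genes for 7 libraries. Of these, 1036 carried no symbol, held between 0.376% and 0.424% of each library's counts, and were left out. A further 26 symbols had been turned into dates by a spreadsheet program and were kept under the date, 19 of them among the genes tested. Total counts per library lay between 26780291 and 34483612. No molecular identifiers were used, so reads copied from the same molecule cannot be told apart. The tests estimate the spread of counts between libraries and do not treat reads as independent molecules. The labels give no sequencing batch, sex or pairing, and they do not say that each library came from a separate mouse, so the p-values measure only the spread between these libraries.

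Libraries were grouped by genotype as labelled, with 4 WT and 3 Cish-/- (KO) libraries, and KO was compared with WT. Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr, which left 12759, libraries were scaled by TMM factors, and a quasi-likelihood F test was run on genotype alone with 5 residual degrees of freedom. The common biological coefficient of variation was 0.187. Genes with a Benjamini-Hochberg adjusted p below 0.05 were called, and a second count required an absolute log2 fold change of at least 1. Expression is given as CPM, counts per library scaled to a common total with the TMM factors. Log2 CPM values used a prior count of 2, and errors are standard deviations (SD) between libraries or standard errors (SE) of the log2 fold change.

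Gene lists were tested with camera of limma 3.58.1 on log2 CPM values, with a preset inter-gene correlation of 0.01, 2-sided, and adjusted over the 20 lists on macrophage biology and, separately, over the 9 testable lists among the 17 on other cell types and sample quality. Lists with fewer than 5 tested members were described by values alone. For each list the number of members past the threshold was also counted with p adjusted over the list alone. Genes near Cish were compared with all other tested genes by Fisher's exact test, 2-sided, in a window of 10 Mb on each side. Gene positions are those of the RefSeq annotation of mm10, and the exons of Cish those of GENCODE M21. Of the tested genes, 12492 were matched to a position by symbol and 126 by synonym, and 141 were not matched.

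The groups, tests, gene lists, alternatives and the rule for which genes to name were set before the data were examined. The rule named Cish, then up to 12 called genes per direction with the largest log2 fold changes, at least 10 CPM in the higher genotype and no overlap of CPM between genotypes, leaving out predicted genes. It also named up to 4 called members of each biology list, or the 2 with the smallest p where none was called, and the most abundant member of each other list with any member that was called. A further set of up to 8 genes per direction was drawn by the same criteria from the DESeq2 calls, and this set, like every gene described as outside the rule, was chosen after the values were seen.

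Alternatives set beforehand were DESeq2 1.42.0 with its size factors, edgeR with RLE factors, upper-quartile factors or library sizes only, no filter, a filter of at least 5 CPM in at least 3 libraries, limma voom with sample quality weights, the replicate number as a block, glmTreat against a fold change of 1.2, each library left out in turn, windows of 5 and 20 Mb, and for the lists an estimated correlation, fry, and camera on the DESeq2 statistics. Alternatives added after the data were seen were the removal of WT 4 and KO 3 together, the count without genes near Cish and Gm8210, the DESeq2 calls near Cish, and the DESeq2 count over the other splits of the libraries. The edgeR test was also tested on simulated data with the dispersion of these libraries and 200 changed genes, where it called 70% of the genes changed 2-fold and 87% of those changed 4-fold, with 8 false calls. On the same simulated counts DESeq2 called 81% and 91%, with 37 false calls. With nothing changed, edgeR made 0 calls and DESeq2 15. The simulated libraries were drawn independently and held no structure shared between particular libraries, so these rates may not hold for the real ones.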

Results

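RNA was sequenced from sorted alveolar macrophages, the resident phagocytes of the airspaces, of 4-month-old C57BL/6 mice. The comparison was between 4 WT libraries and 3 libraries of Cish-/- (KO) mice. Cish encodes a SOCS family protein that is induced through STAT5 and restrains cytokine receptor signalling. The series asks what this brake on resting cytokine signals does to the macrophage identity and function typical of the lung. Total counts were 34483612, 30637634, 31207798 and 33405694 in WT 1 to WT 4, and 30989230, 26780291 and 27478864 in KO 1 to KO 3.

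The first question was whether the targeted gene and its surroundings differed between the genotypes. Reads of Cish were fewer in KO, with 45.5 CPM ± 16.4 (SD, n = 4) in WT and 12.7 CPM ± 1.73 (SD, n = 3) in KO, 3.58-fold lower and without overlap between libraries. The raw counts were 1656, 948, 1198 and 2170 in WT and 390, 369 and 296 in KO, so reads of the gene were present in every KO library. Cish lies on chromosome 9 at 107296026 to 107302784 (mm10) and has 3 exons in its Cish-201 transcript; counts per gene do not show which exons the remaining KO reads came from. The log2 fold change of -1.84 (SE 0.26) missed the edgeR threshold, with an adjusted p of 0.0519. DESeq2 gave -1.85 with an adjusted p of 2.81e-11, and edgeR passed without WT 2 (adjusted p 0.0266), without WT 4 (0.0126) and without KO 3 (0.0376). On all 7 libraries Cish also passed with library sizes only (0.0277), no filter (0.000161), the stricter filter (0.0474) and voom of limma (0.0454). It also passed with the replicate block (0.0107), in which WT 4 has its own level and so takes no part in the comparison. It passed in 10 of 16 alternatives, over which the adjusted p ranged from 2.81e-11 to 0.225.

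Close to Cish, 4 genes fell in KO. Rpl29, a protein of the large ribosomal subunit (chromosome 9, 106428889 to 106431568), fell by 3.22 on the log2 scale (SE 0.14, edgeR adjusted p 6.83e-06), from 34.9 CPM ± 2.52 (SD, n = 4) to 3.73 CPM ± 0.602 (SD, n = 3). Abhd14b, an alpha/beta hydrolase (106447737 to 106452923), went from 21.8 CPM ± 0.674 to 3.20 CPM ± 0.201, a log2 fold change of -2.76 (SE 0.11). Alas1, the rate-limiting enzyme of heme synthesis (106233455 to 106247954), fell 4.25-fold, from 668 CPM ± 59.6 to 157 CPM ± 9.79, with an edgeR adjusted p of 1.81e-05. Parp3, an ADP-ribosyltransferase (106470322 to 106476949), fell 3.05-fold, from 57.6 CPM ± 6.67 to 18.9 CPM ± 0.864, with an edgeR adjusted p of 0.000301. Within 10 Mb of Cish, 4 of 153 tested genes were called (2.61%), against 7 of 12464 elsewhere (0.0562%), an odds ratio of 47.6 with a p of 6.42e-06 by Fisher's exact test. The test treats neighbouring genes as independent of one another. The median log2 fold change of the 153 genes was -0.01.

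Gm8210, a predicted gene on chromosome 1 (43189052 to 43189773), rose by a log2 fold change of 2.82 (SE 0.11, edgeR adjusted p 6.83e-06), from 3.61 CPM ± 0.077 to 25.5 CPM ± 1.82; it lies outside the naming rule and was chosen after its values were seen. RefSeq lists it as a pseudogene with Rpl29 among its synonyms. The summed counts of Rpl29 and Gm8210 were 38.5 CPM ± 2.59 in WT and 29.2 CPM ± 2.41 in KO, a log2 fold change of -0.40 (SE 0.09). The sum was not called by edgeR (adjusted p 0.0979). Reads of Rpl29 counted for Gm8210 could account for most of the lower Rpl29 count.

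**Figure D1:**
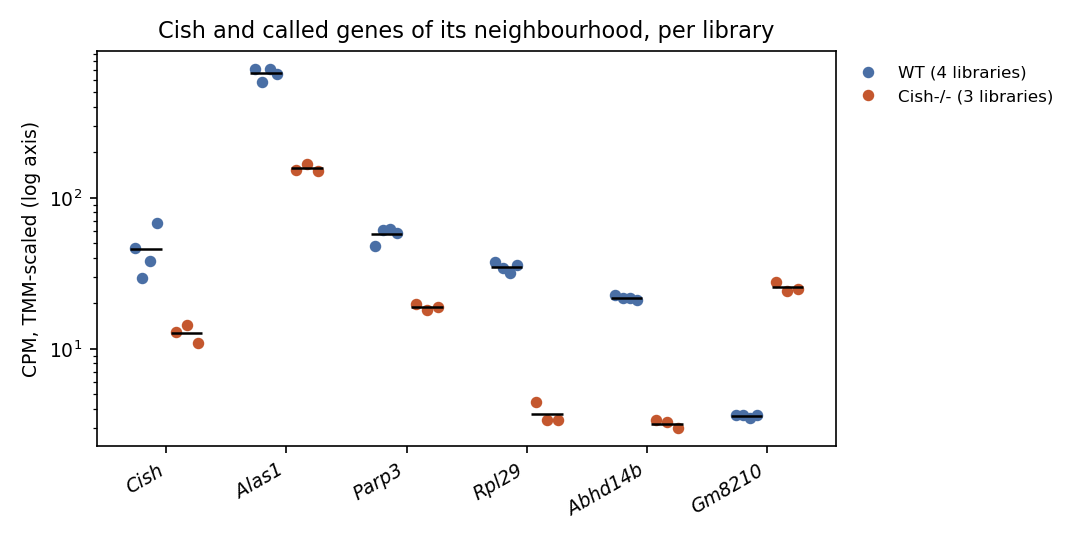
Expression in CPM, on a log axis, of Cish, its called neighbours Alas1, Parp3, Rpl29 and Abhd14b, and of Gm8210 in each WT and KO library. Points are libraries and bars are group means; WT and KO libraries do not overlap for any of the 6 genes.

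**Figure D2:**
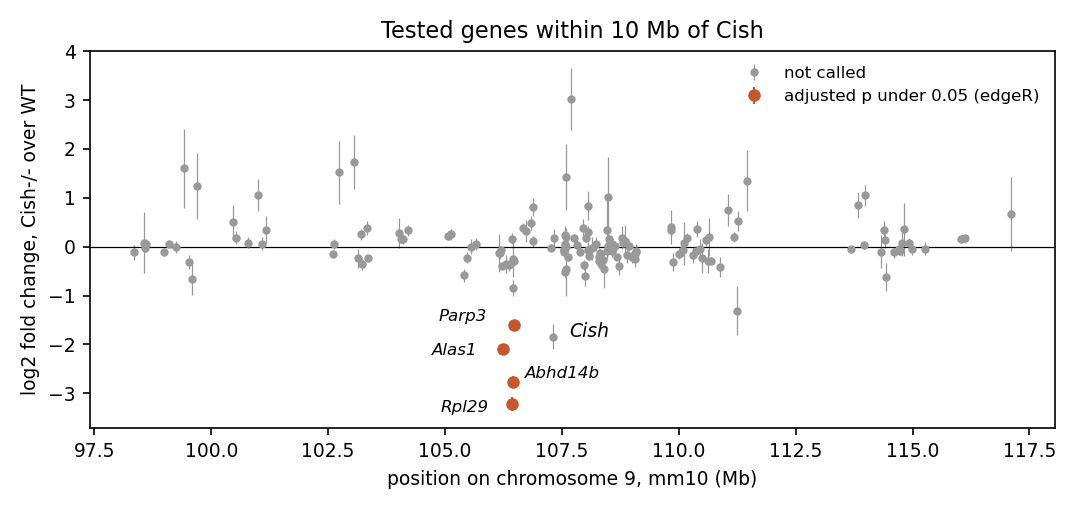
Log2 fold change of KO over WT, with SE, of the 153 tested genes within 10 Mb of Cish against their position on chromosome 9 (mm10). The 4 called genes, in orange, lie together on one side of Cish, while the median of all 153 genes is -0.01.

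Across the genome, few single genes passed the edgeR test. Siglece, an inhibitory receptor that binds sialic acid (chromosome 7, 43648882 to 43672044), fell 2.20-fold, from 63.7 CPM ± 5.45 (SD, n = 4) to 28.9 CPM ± 3.85 (SD, n = 3), with an edgeR adjusted p of 0.00565. Mmp8, a collagenase best known from neutrophils (chromosome 9, 7558429 to 7568486), rose 2.27-fold, from 69.5 CPM ± 7.37 to 158 CPM ± 37.4, with an edgeR adjusted p of 0.0427. Lilr4b, a leukocyte immunoglobulin-like receptor (chromosome 10, 51480612 to 51486329), rose 1.78-fold, from 333 CPM ± 40.9 to 591 CPM ± 32.9, with an edgeR adjusted p of 0.0334. Its paralog Lilrb4a had a log2 fold change of 0.53 and an adjusted p of 0.0519, and reads of the pair may be shared.

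Outside the naming rule, and chosen after their values were seen, Hs3st3b1, Gm4951 and C2 also rose. Hs3st3b1, a heparan sulfate sulfotransferase, went from 0.796 to 9.69 CPM (edgeR adjusted p 0.00948), Gm4951 from 0.878 to 10.2 CPM (0.0288) and the complement gene C2 from 0.332 to 2.44 CPM (0.0420). In all, edgeR called 11 of 12759 genes, 6 higher and 5 lower in KO, of which 10 had an absolute log2 fold change of at least 1. The calls of Mmp8, Lilr4b, Gm4951 and C2 ended without WT 1 (adjusted p 0.0959 to 0.114), WT 2 (0.126 to 0.147), KO 1 (0.0701 to 0.206) or KO 2 (0.0527 to 0.0871), and those of Mmp8, Gm4951 and C2 without WT 3 (0.0812 to 0.0981). Without genes within 10 Mb of Cish and without Gm8210 the count was 6.

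DESeq2 called 753 genes, 354 higher and 399 lower in KO, which held all 11 edgeR calls. Among those with an absolute log2 fold change of at least 1, 165 were higher and 66 lower. The genes with the largest changes among them were drawn by the same criteria after the values were seen. Higher in KO by DESeq2 were the secreted glycoprotein Fstl1 (log2 fold change 3.90, adjusted p 1.22e-05), the receptor Cd200r2 (3.21, 4.24e-05), the eosinophil-associated ribonuclease Ear6 (2.78, 0.000512), Wfdc17 (2.34, 0.0444), the cholesterol 25-hydroxylase Ch25h (2.22, 0.00368), the scavenger receptor Msr1 (1.98, 0.00195), the chemokine receptor Cxcr1 (1.95, 0.0294) and the aldo-keto reductase Akr1b8 (1.92, 3.9e-05). Lower by DESeq2, beside Rpl29, Abhd14b and Alas1, were the MHC class II regulator Ciita (-2.37, 0.00313), the integrin subunit Itgad (-2.07, 0.00884), the serine protease Htra3 (-2.07, 0.00242), the keratin Krt80 (-1.94, 0.00953) and the MHC class II chain H2-Aa (-1.90, 0.0127). By edgeR, 2296 genes had an unadjusted p below 0.05, where 638 would by chance. Groups did not overlap for 2036 genes (16.0%), against 5.71% by chance. Both chance values are averages. Genes vary together across these libraries, so a single split can lie far above them, and neither count was made for the other splits.

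The number of genes called rested on particular libraries. On the first principal component, with 42.6% of the variance, WT 4 lay at 7.27, between the other WT libraries (-39.4 to -24.1) and the KO libraries (18.3 to 43.9). Without WT 4 edgeR called 284 genes, without KO 3 it called 217 and without WT 1 it called 7. WT 4 and KO 3 stand after the other 5 libraries in the deposited table, though the labels give no batch. Among those 5 libraries alone, a choice made after seeing the data, edgeR called 590 genes, with 349 higher and 241 lower, and with a term for WT 4 and KO 3 it called 19 over all 7.

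**Figure D3:**
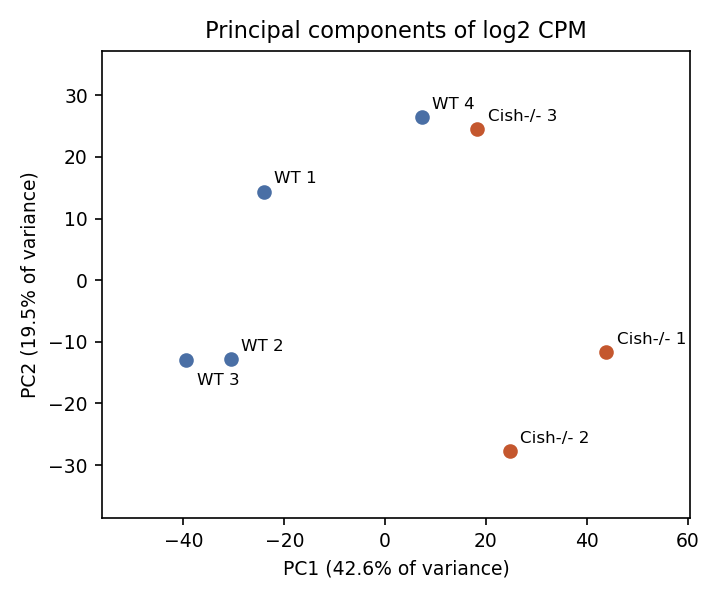
Principal components of log2 CPM values of the 7 libraries, with 42.6% of the variance on the first and 19.5% on the second; points are libraries. WT 4 lies at 7.27 on the first component, nearer to KO 3 at 18.3 than to the nearest other WT library at -24.1.

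The next question was which functions of the macrophages moved with genotype. Of the 20 lists, MHC class II genes fell, and unfolded protein response, type I interferon and NF-kB inflammatory genes rose, by camera. None of the 4 calls was kept with an estimated correlation, where 0 lists were called and 0 had an unadjusted p below 0.05 (fry: 0 called, 4 at an unadjusted p below 0.05). Of the 35 ways to split the 7 libraries into 4 and 3, the real one included, 23 gave at least 4 called lists. Of the 420 members of the 20 lists, edgeR called 0 over all genes tested. An unadjusted p below 0.05 was found for 118 members, and DESeq2 called 49. Among all genes, 2296 of 12759 had such a p by edgeR and DESeq2 called 753 of 13198. Passes of single genes given below without WT 4 or without KO 3 come from fits that called 284 and 217 genes in all.

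MHC class II genes, which present peptides to helper T cells, fell as a list: 12 of 13 were lower in KO, with a median log2 fold change of -0.66 (adjusted p 8.19e-05 with the preset and adjusted p = 0.546 with an estimated correlation, camera of limma). Ciita, the master regulator of the class, had 13.9 CPM in WT and 2.70 in KO (log2 fold change -2.36, SE 0.50, edgeR adjusted p 0.0950). H2-DMb1, which helps load peptides, had 281 and 153 CPM (-0.87, adjusted p 0.0950). The chain H2-Aa had a log2 fold change of -1.89, and H2-Ab1 and the invariant chain Cd74, chosen after their values were seen, of -1.85 and -1.69. DESeq2 called 8 members, all lower, and 8 passed when adjusted over the list alone. The summed CPM of the list were 6083 ± 1986 (SD, n = 4) in WT and 2313 ± 1027 (SD, n = 3) in KO. WT 1 stood at 3373 CPM, level with KO 3 at 3367, and the other WT libraries at 5927 to 7940; Cd74 was at 1710 CPM in WT 1 and 1858 in KO 3. Ciita passed edgeR without WT 4 (adjusted p 0.0496), and H2-Aa, H2-Ab1 and Cd74 without KO 3 (0.0450 to 0.0463). Each of these genes passed in 5 of 16 alternatives.

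Unfolded protein response genes, chiefly chaperones of the endoplasmic reticulum, rose as a list: 16 of 17 were higher in KO, with a median log2 fold change of 0.32 (camera adjusted p 8.19e-05, limma). The list had an adjusted p = 0.546 with an estimated correlation, and its median was 0.20 without KO 1. Hspa5, the main chaperone of that compartment, had 2061 CPM ± 343 (SD, n = 4) in WT and 3261 ± 478 (SD, n = 3) in KO (log2 fold change 0.66, SE 0.15, edgeR adjusted p 0.0970). Syvn1, a ubiquitin ligase of protein degradation there, had 66.2 and 110 CPM (0.74, or 0.49 without KO 1, adjusted p 0.0975). By DESeq2, Dnajb9, Dnajc3, Syvn1, Hspa5, Pdia4 and Herpud1 were higher and no member was lower; 6 passed when adjusted over the list alone. Hspa5 passed edgeR without WT 4 (adjusted p 0.0488) and without KO 3 (0.0459), and passed in 6 of 16 alternatives.

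Type I interferon genes rose as a list, with 24 of 25 higher in KO and a median log2 fold change of 0.32 (camera adjusted p 0.000423, limma). The adjusted p = 0.546 with an estimated correlation. Ifitm3, an antiviral membrane protein, had only 2.56 CPM in WT and 5.73 in KO (log2 fold change 1.16, edgeR adjusted p 0.111). Usp18, which removes ISG15 from proteins, had 1.09 and 3.07 CPM (1.49, adjusted p 0.125), with KO 2 at 1.44 and WT 1 at 1.34. The median was 0.55 without KO 2 and 0.14 without KO 3. The mean log2 CPM of the list was 3.47, 3.20 and 3.79 in KO 1 to KO 3. In WT it was 2.60 in WT 2 and 3.11 to 3.20 in the others, so KO 2 was level with WT 1. DESeq2 called Oas1a, Usp18 and Ifitm3, all higher, and when adjusted over the list alone 0 of 25 passed by edgeR.

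NF-kB inflammatory genes rose as a list, with 20 of 24 higher in KO and a median log2 fold change of 0.51 (camera adjusted p 0.0119, limma). The adjusted p = 0.548 with an estimated correlation. Cxcl3, a neutrophil-attracting chemokine, had 12.5 CPM in WT and 27 in KO (log2 fold change 1.11, edgeR adjusted p 0.0519), and the cytokine Il1a had a log2 fold change of 0.85 (adjusted p 0.178). DESeq2 called Il1b and Cxcl3, both higher, and 1 member passed when adjusted over the list alone. The mean log2 CPM of the list was 6.14 and 6.00 in KO 1 and KO 2 but 5.14 in KO 3, within the WT range of 5.09 to 5.53. Il1a was at 434, 581 and 204 CPM in KO 1 to KO 3 and at 204 to 265 CPM in WT, with a log2 fold change of 0.49 without KO 2, and passed edgeR without KO 3 (1.17, adjusted p 0.0128). The call of the list ended without WT 4 (median 0.36, adjusted p 0.0794) and without KO 1 (0.18, 0.166), and Cxcl3 passed without WT 3 (0.0494), WT 4 (0.0320) or KO 3 (0.0362).

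**Figure D4:**
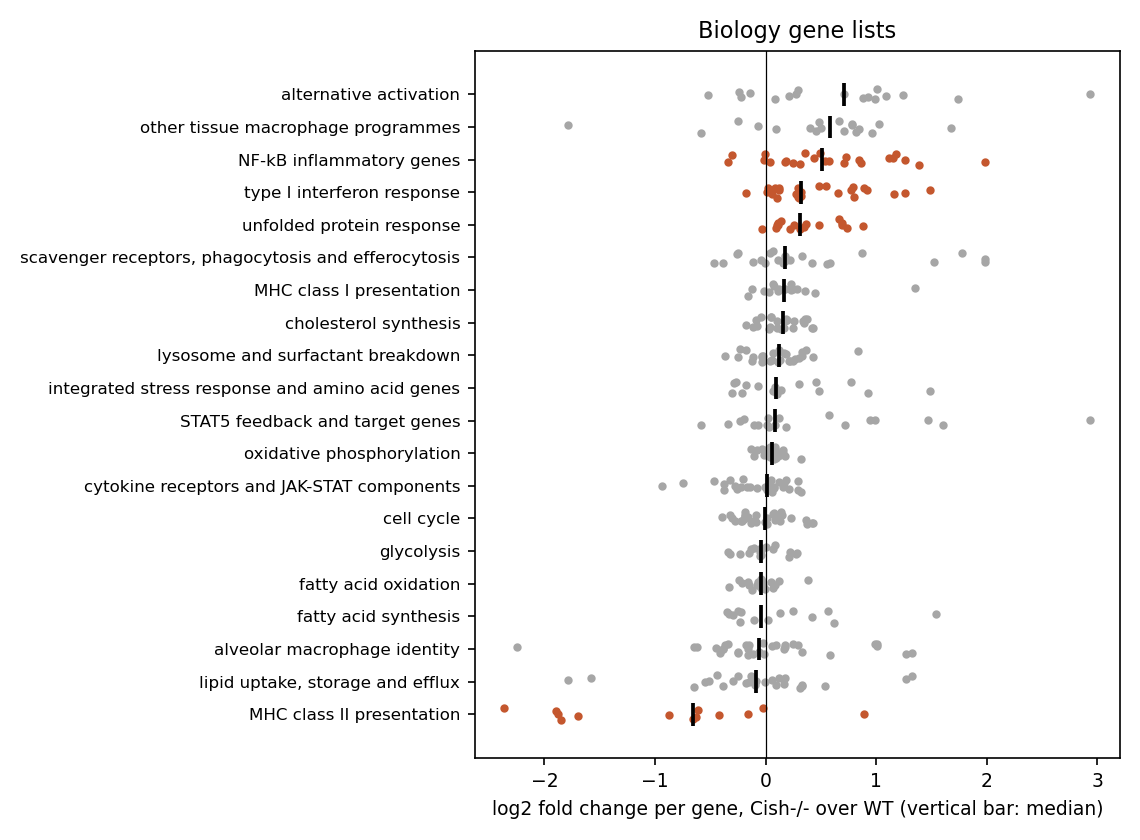
Log2 fold change of KO over WT of the tested members of the 20 biology lists; each point is a gene and the bar the list's median. In orange are the 4 lists past camera's threshold with the preset correlation: MHC class II (median -0.66), unfolded protein response (0.32), type I interferon (0.32) and NF-kB (0.51).

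**Figure D5:**
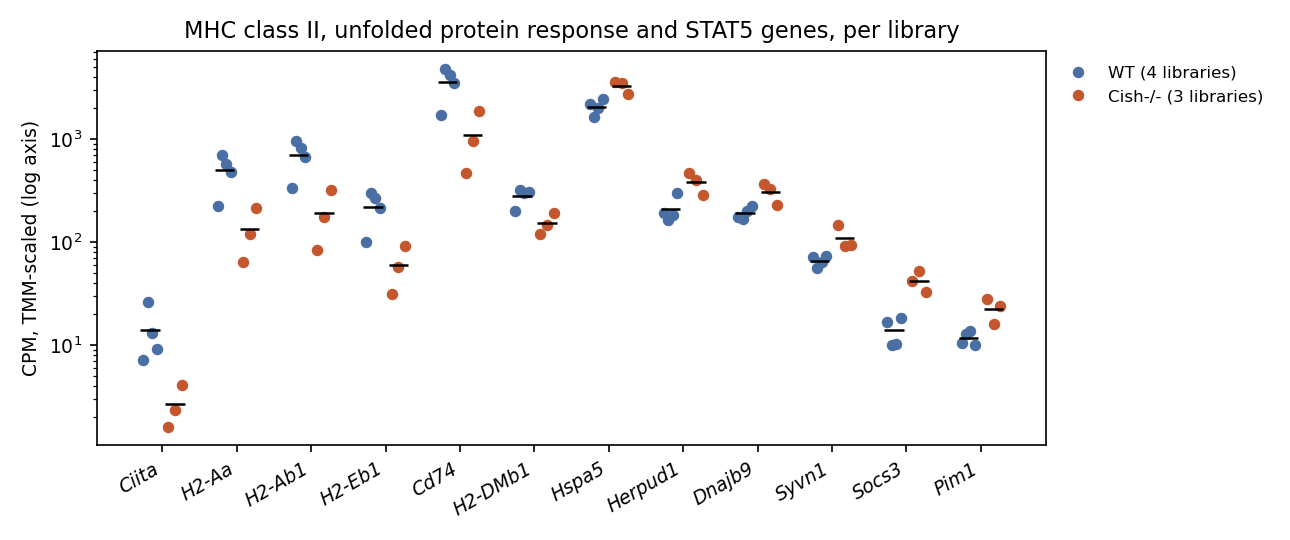
Expression in CPM, on a log axis, of MHC class II genes, unfolded protein response genes and the STAT5 feedback genes Socs3 and Pim1 in each library. Points are libraries and bars are group means, for example 13.9 CPM in WT and 42.4 CPM in KO for Socs3.

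Feedback and target genes of STAT5, the pathway Cish restrains, did not pass as a list with the edgeR values: 13 of 19 were higher, with a median log2 fold change of 0.08 and a mean of 0.43 (camera adjusted p 0.166, limma). The median was 0.05 without WT 4, 0.20 without KO 1 and -0.02 without KO 2, and the list passed on the DESeq2 statistics (adjusted p 0.0263). Socs3, a feedback inhibitor of cytokine receptors, had 13.9 CPM ± 4.37 (SD, n = 4) in WT and 42.4 ± 9.55 (SD, n = 3) in KO, a log2 fold change of 1.60 (SE 0.24) with an adjusted p of 0.0561 by edgeR and 1.56e-08 by DESeq2. It passed edgeR without WT 4 (adjusted p 0.0247) and without KO 3 (0.0189), and passed in 8 of 16 alternatives. The survival kinase Pim1 had 11.8 and 22.6 CPM (log2 fold change 0.94), with an adjusted p of 0.0950 by edgeR and 0.000512 by DESeq2. DESeq2 called 2 members higher and 1 lower, and 4 passed when adjusted over the list alone. Cytokine receptors and JAK-STAT components went both ways, with 15 of 29 higher, a median of 0.01, a mean of -0.09 and a test direction of lower (camera adjusted p 0.328). Their median lay between -0.07 (without KO 3) and 0.03 (without KO 2) and was -0.02 without WT 3, and the list passed on the DESeq2 statistics (0.0475). Csf3r, the G-CSF receptor, had a log2 fold change of -0.94 and Il3ra, the IL-3 receptor alpha chain, of -0.75, both lower by DESeq2 (adjusted p 0.00421 and 0.0138); adjusted over the list alone, 0 of the 29 passed edgeR, with 9 at an unadjusted p below 0.05 and 3 called by DESeq2.

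Genes typical of alveolar macrophages showed no net shift as a list, with a test direction of lower (camera adjusted p 0.328, limma). Of 33 members 14 were higher, with a median log2 fold change of -0.06 (from -0.15 without KO 2 to 0.01 without KO 1) and a mean of 0.02. Changes in opposite directions can cancel in this test. Single members went both ways, and 12 passed when adjusted over the list alone. An unadjusted p below 0.05 by edgeR was found for 17 of the 33, against 2296 of all 12759 genes. The zinc transporter Slc39a2 had 128 CPM in WT and 257 in KO, with an adjusted p of 0.0797 by edgeR and 1.73e-05 by DESeq2. Cidec, a lipid droplet protein, had 595 and 381 CPM, with an adjusted p of 0.0898 by edgeR and 0.00017 by DESeq2. DESeq2 called 6 members lower, among them Siglecf, the surface receptor commonly used to identify these cells, Krt19, Ear1 and Cd2, and 2 higher, Slc39a2 and Mrc1. Slc39a2 passed edgeR without WT 4 (adjusted p 0.0362) and without KO 3 (0.0376), and passed in 7 of 16 alternatives. Genes typical of other tissue macrophages had 14 of 18 higher and a median of 0.58 (camera adjusted p 0.0711), and the list passed without KO 3 (0.0169) and on the DESeq2 statistics (0.0336). Gpnmb, a membrane glycoprotein of lipid-laden macrophages, had 513 and 1003 CPM, and the lipid receptor Trem2 41.5 and 74.7 CPM; both were higher by DESeq2 (adjusted p 0.00195 and 0.0249). In KO 3 Gpnmb was at 624 CPM, below WT 1 at 631. Trem2 in KO 3 was at 45.7 CPM, within the WT range of 31.1 to 56.1, and its log2 fold change went from 0.85 to 0.53 without KO 1. The mean log2 CPM of the list was highest in WT 4, at 3.01, against 2.99, 2.71 and 2.76 in KO 1 to KO 3. The other WT libraries were at 1.86 to 2.29.

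Lists of lipid metabolism did not pass camera with the edgeR values. Cholesterol synthesis had 19 of 24 members higher (median log2 fold change 0.16, adjusted p 0.266, limma), with Insig1 at 0.42 and Hmgcs1 at 0.43 (0.28 without KO 3), and the list passed without KO 2 (median 0.37, adjusted p 0.000403) and on the DESeq2 statistics (0.0498). Its median was 0.07 without WT 2, 0.23 without WT 4 and -0.17 without KO 3. Lipid uptake, storage and efflux had 11 of 26 higher (median -0.09, or -0.02 without KO 1 and -0.21 without KO 2, adjusted p 0.378), where 5 passed adjusted over the list alone; Dgat1, which makes triglycerides, had a log2 fold change of 0.53 and was higher by DESeq2 (adjusted p 0.00627). Fatty acid oxidation had 5 of 21 higher (median -0.04, or -0.01 without WT 1, -0.09 without KO 2 and -0.02 without KO 3, adjusted p 0.328), with Acadl at 0.38 (0.25 without KO 1) and Slc25a20 at -0.21. Fatty acid synthesis had 7 of 14 higher, a median of -0.04, a mean of 0.13 and a test direction of lower (adjusted p 0.841). Its median was 0.07, 0.00 and 0.10 without WT 1, KO 1 and KO 2, and -0.19 without KO 3. Fads2 was at 1.54 (0.72 without KO 3) and Elovl5, which lengthens fatty acids, at -0.35 and lower by DESeq2 (adjusted p 0.0142).

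Lysosomal genes had 18 of 28 members higher (median log2 fold change 0.12, or 0.03 without KO 1 and 0.19 without KO 3, camera adjusted p 0.184, limma). Ctsk, a lysosomal collagen-degrading protease, had 628 CPM in WT and 1122 in KO, with an adjusted p of 0.0950 by edgeR and 0.000435 by DESeq2, and Tfeb, a regulator of lysosomal genes, was at -0.37. Glycolysis had 7 of 18 higher (median -0.04, or 0.00 without WT 4 and -0.08 without KO 1, adjusted p 0.732), with Slc16a3 at -0.33 and Pgam1 at 0.28 (0.18 without KO 1). Oxidative phosphorylation had 23 of 29 higher (median 0.06, or 0.02 without KO 1 and 0.09 without WT 4, adjusted p 0.184), with Idh3a at 0.32.

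MHC class I genes had 14 of 17 members higher (median log2 fold change 0.17, camera adjusted p 0.0691, limma), and the list passed without WT 1 (0.0478), WT 4 (0.00249) or KO 3 (0.0486) and on the DESeq2 statistics (0.0260). Its median was 0.11 without WT 2 and 0.07 without KO 1. Nlrc5, the regulator of the class, was at 1.35 and higher by DESeq2 (adjusted p 0.00125), and H2-T23 at 0.36. Alternative activation genes had 13 of 17 higher (median 0.71, adjusted p 0.128), with Mrc1, the mannose receptor, at 0.29 and Pdcd1lg2 at -0.52; the list passed without WT 4 (median 0.60, adjusted p 0.0232) and without KO 2 (1.18, 0.00542), and had a median of 0.04 without KO 3 (0.522) and of 0.31 to 0.33 without WT 1, WT 2 or WT 3. Scavenger and phagocytosis receptors had 16 of 23 higher (median 0.17, adjusted p 0.180), and 5 passed adjusted over the list alone. Msr1 had 16.9 CPM in WT and 66.7 in KO. It passed edgeR without WT 4 (adjusted p 0.0445) and without KO 3 (0.0128), and passed in 5 of 16 alternatives. The high-affinity IgG receptor Fcgr1 was at -0.47 and lower by DESeq2 (adjusted p 0.00318).

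Cell cycle genes had 15 of 31 members higher (median log2 fold change 0.00, from -0.08 without WT 3 to 0.05 without WT 1, camera adjusted p 0.830, limma), with Birc5 at -0.40 and Mcm3 at 0.36, both called by DESeq2 (adjusted p 0.00985 and 0.0328). Integrated stress response genes had 10 of 16 higher (median 0.10, adjusted p 0.266), with 6 passing when adjusted over the list alone. Their median ran from 0.04 without KO 1 to 0.17 without KO 3, and the list passed on the DESeq2 statistics (0.0456). Asns, the asparagine synthetase, was at 1.48 and Shmt2 at 0.30, and DESeq2 called Ddit3, Slc7a11, Asns and Mthfd2 higher and no member lower.

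Markers of other cells were mostly scarce beside the macrophage genes. Endothelial markers rose as a list (median log2 fold change 1.65, camera adjusted p 2.35e-05, limma; adjusted p = 0.514 with an estimated correlation), and their 7 genes summed to 13.7 CPM ± 2.52 (SD, n = 4) in WT and 26.2 ± 6.90 (SD, n = 3) in KO. The most abundant, Vwf, had 11.03 and 17.5 CPM (log2 fold change 0.67, or 0.42 without KO 1), and 7 passed adjusted over the list alone. Neutrophil markers summed to 83.3 CPM ± 5.49 in WT and 181 ± 47.0 in KO, most of it Mmp8. Erythroid markers summed to 192 ± 171 and 562 ± 286 CPM, led by Hba-a2, and airway epithelial markers to 8.16 ± 5.88 and 25.3 ± 18.7 CPM, led by Scgb1a1; both had too few tested members for a list test. Alveolar type 2 markers had 6 of 8 members higher and a median of 0.90 (adjusted p 0.241), and the list passed with the replicate block (0.00277) and without WT 4 and KO 3 together (0.0309), while its median was 0.38 without KO 1. Their sums of 151 CPM in WT and 152 in KO hide this, since Napsa, the most abundant, had 94.1 and 64.2 CPM, with 39.8 CPM in KO 1 and 103 in KO 3. Its log2 fold change of -0.55 was -0.30 without KO 1 and passed edgeR without KO 3 (-1.07, adjusted p 0.0375). Type 1 markers summed to 127 and 124 CPM (0.819), led by Cav1. Fibroblast and smooth muscle markers summed to 6.52 and 11.6 CPM (0.169), led by Acta2, and T cell markers to 4.82 and 7.89 (0.169), with Lck highest over both genotypes; both lists passed without KO 3 (0.00272 and 0.0393).

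B cell markers summed to 16.0 CPM ± 7.17 (SD, n = 4) in WT and 16.0 ± 14.7 (SD, n = 3) in KO, with Ighm highest over both. The sums were 8.29, 33.0 and 6.77 CPM in KO 1 to KO 3 and 5.26 (WT 4) to 20.5 CPM (WT 2) in WT. The median log2 fold change was -0.02 (from -0.33 without WT 3 to 0.39 without WT 1), with a test direction of higher (camera adjusted p 0.819, limma). Dendritic cell markers, among the cells rich in MHC class II, summed to 18.5 CPM ± 2.16 in WT and 16.9 ± 7.06 in KO (0.819), led by Batf3. NK cell markers summed to 1.72 and 4.41 CPM; Klrb1c, the highest over both genotypes, averaged 0.154 CPM in WT and had 2.94, 3.92 and 0.147 CPM in KO 1 to KO 3 and passed edgeR without KO 3 (adjusted p 0.0128). Eosinophil markers summed to 122 and 107 CPM with Cd24a first, the mast cell marker Cpa3 had 0.340 and 0.375 CPM and the platelet marker Pf4 3.01 and 6.11 (log2 fold change 1.02, or 0.46 without KO 3). Monocyte markers had a median of 0.18 (from 0.12 without WT 3 to 0.36 without KO 2, adjusted p 0.669); Chil3, also a gene of alveolar macrophages, took 1.74% to 4.85% of counts in WT and 3.91% to 7.17% in KO, and passed edgeR without WT 4 (adjusted p 0.0445). Of the sex-linked genes, the Y-linked Eif2s3y had 97.3 CPM in WT and 88.2 in KO and was present in all 7 libraries. Immediate early and heat shock genes, a sign of handling stress, had a median of 0.24 (adjusted p 0.236), and the list passed without WT 3 (0.0400) and without KO 1 (0.0133) but had a median of -0.12 without KO 2 and of 0.41 without KO 3. Its most abundant member Hspa1b took, with Hspa1a, 0.382% to 1.29% of counts in WT and 0.596% to 2.87% in KO.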

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

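The exchange test and the batch term below were chosen only after the result was seen. Among 132 values per library in the 4 WT libraries, 7 had a lowest or highest library far from the others by Dixon's ratio, past its 95% critical value; chance gives about 1 in 20, here 6.6. The share of counts in ribosomal protein genes was 0.438% in WT 3 and 0.471% to 0.477% in the other WT libraries (ratio 0.850). Elovl5 was at 210 CPM in WT 2 and 192 to 193 CPM in the others (ratio 0.989). H2-T23, an MHC class I gene, was at 205 CPM in WT 4 and 142 to 149 CPM in the others (ratio 0.893). Lilrb4a was at 913 CPM in WT 3 and 825 to 835 CPM in the others (ratio 0.886). The type I interferon list had a mean log2 CPM of 2.60 in WT 2 and 3.11 to 3.20 in the others (ratio 0.839). The alternative activation list was at 5.04 in WT 4 and 2.92 to 3.00 in the others (ratio 0.959), and the monocyte marker list at 2.71 in WT 3 and 3.57 to 3.58 in the others (ratio 0.982).

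The number of genes called rose from 11 to 284 without WT 4 and to 217 without KO 3. An exchange or mixing of these libraries with the other genotype was argued against by Cish (67.9 CPM in WT 4, 10.9 CPM in KO 3) and the 4 genes near it with the smallest p without both libraries: on a scale of 0 for the other WT and 1 for the other KO libraries, WT 4 had a median position of -0.0195 and KO 3 of 1.06 over these 5 genes. WT 4 and KO 3 stand last in the deposited table. A batch that adds alike to both was argued against by edgeR with a term for the 2 libraries, which called 19 genes. Without the 10 most abundant genes edgeR called 12. TMM factors already limit the weight of such genes, so this count had little room to move and does not decide on them. On the second principal component, with 19.5% of the variance, WT 4 (26.4) and KO 3 (24.5) lay together, above WT 1 (14.3). The other libraries lay at -27.7 to -11.7. In log2 CPM, WT 4 correlated more with KO 3 (r 0.987) than with the other WT libraries (0.974 to 0.981). These values leave batches of another form open. A difference in macrophage state between libraries within each genotype is a biological explanation that was not tested. A split of WT 1, WT 2 and WT 3 against the other 4 libraries called more genes than the real one, which points to a structure of the samples with WT 4 near the KO libraries.

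Chance could not be excluded for the number of edgeR calls, since 2 of the 35 splits of the libraries, the real one included, gave as many (real 11, highest other 124). The same held for calls with an absolute log2 fold change of at least 1 (2 splits, real 10, highest other 73), for DESeq2 calls (2 splits, real 753, highest other 924) and for called biology lists (23 splits, real 4, highest other 10). For edgeR calls within 10 Mb of Cish, 1 of the 35 splits, the real one, gave as many (real 4, highest other 1), which argued against chance there. This is the smallest share that 35 splits can give, and several counts were tested this way. The 4 genes also lie close together, so chance was not excluded.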

How the results depend on the processing

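The removal of WT 4 and KO 3 together and the count without genes near Cish were chosen only after the result was seen. RLE factors, upper-quartile factors and, except for Cish, library sizes only kept every count within 1.5 times its value. They gave 11, 11 and 12 genes, the last with 41.7% higher against 54.5%, and glmTreat called 8 genes. The odds ratio near Cish stayed past its threshold at 63.1 (5 Mb), 27.6 (20 Mb) and 2.18 (DESeq2 calls). Each of these holds the same 4 edgeR calls, so they are not separate tests. Without the edgeR calls the DESeq2 odds ratio was 1.71 (p 0.0728 by Fisher's exact test). With DESeq2, 753 genes were called, 231 with an absolute log2 fold change of at least 1, Cish was at -1.85, 10 biology and 2 other lists were called. Without a filter the values were 397, 179 and -1.85, with 2 other lists. With the stricter filter they were 21 (71.4% higher), 16 and -1.82, with 0 other lists called by camera (DESeq2 2). That filter left too few endothelial markers for a test, so its 0 says nothing on the endothelial call. With voom they were 46, 27 and -1.70, with 8 biology and 2 other lists. With the replicate block they were 430, 241 and -1.57, with 4 other lists; the numbers did not pair the libraries, since deviations of same-numbered libraries correlated across genes with r -0.00828, 0.142 and -0.0173 (genes are not independent replicates). Without WT 4 and KO 3 they were 590, 335 and -1.48, with 8 biology and 5 other lists. Cish was at -1.88 with library sizes only, and the count was 6 without genes near Cish and Gm8210. An estimated correlation and fry each gave 0 biology and 0 other lists. With 1 library left out, 7 to 284 genes, 7 to 150 of at least 1, Cish at -1.999 to -1.58, 3 to 6 biology and 1 to 3 other lists were found. Of 1378 values of the 88 named genes, those of Cish left out, 1146 kept their side of the threshold, 212 passed it newly and 20 no longer passed. Among the 1146, 7 changed sign, and 0 values of called genes reversed. Of 515 list values, 465 kept their side of the threshold, 37 passed it newly, 13 no longer passed and 0 called ones reversed. Without KO 3, 28 of the single genes newly passed, and without WT 4, 22. The median of 11 of 29 lists, 0 of them called by camera, changed sign with 1 library left out. Apart from the tests of the rise without WT 4 or KO 3 given above, the cause was not tested.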

Other observations

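The tests on a stretch of another strain's chromosome, on the sum of Rpl29 and Gm8210 and on clusters with the genes noticed first were chosen only after the result was seen, as were the genes described here. With the 4 edgeR calls included, DESeq2 called 18 of 153 tested genes within 10 Mb of Cish (11.8%) against 718 of 12464 elsewhere (5.76%), with an odds ratio of 2.18 and a p of 0.00451 by Fisher's exact test. They went both ways. Manf, a secreted factor of the unfolded protein response that was left out of that list for its position, had 183 CPM ± 38.9 (SD, n = 4) in WT and 320 CPM ± 63.4 (SD, n = 3) in KO, with an adjusted p of 0.0950 by edgeR and 0.00102 by DESeq2. Twf2, an actin-binding protein, had 107 and 81.1 CPM, with an adjusted p of 0.0718 by edgeR and 7.22e-05 by DESeq2. Gpx1, a glutathione peroxidase, had 1905 and 1486 CPM, with an adjusted p of 0.110 by edgeR and 0.0074 by DESeq2.

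The calls near Cish, Rpl29, Abhd14b, Alas1 and Parp3, were weighed against a stretch of another strain's chromosome 9 carried along with the mutation, against reads shared with a pseudogene, and against an effect on the whole neighbourhood. A shift of all genes there was argued against by their median log2 fold change of -0.00704, inside the central 95% of runs of as many genes elsewhere (-0.06 to 0.07). Reads of Rpl29 counted for Gm8210 were argued against as the whole cause of the lower Rpl29 by the log2 fold change of their sum, -0.40 (SE 0.09). The sum was not called by edgeR (adjusted p 0.0979), and the gain of Gm8210 could account for most of the loss. Reads of Rpl29 counted for other copies, or dropped for mapping to several places, were not tested. A strain stretch may hold further changed genes, and among genes not called by edgeR, DESeq2 called 14 of 149 near Cish (9.40%) against 711 of 12457 elsewhere (5.71%), an odds ratio of 1.71 (95% confidence interval 0.907 to 3.00, p 0.0728 by Fisher's exact test), which leaves it open. An effect of the mutation itself on nearby genes was not tested.

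Several genes stood at unlike levels among the 3 KO libraries and differed less among WT libraries. Clec1b, a C-type lectin receptor, was at 110, 117, 125 and 177 CPM in WT 1 to WT 4 and at 4.62, 4.47 and 159 CPM in KO 1 to KO 3. Lrmda was at 17.5 to 18.6 CPM in WT and at 2.18, 2.56 and 16.7 CPM in KO 1 to KO 3. The kinase Stk25 was at 62.7 to 73.0 CPM in WT and at 25.9, 20.4 and 67.0 CPM in KO 1 to KO 3. Nav1 was at 16.2 to 38.7 CPM in WT and at 2.24, 2.72 and 21.4 CPM in KO 1 to KO 3. Klrb1c, near Clec1b on chromosome 6 (start at 128778485 against 129397297), averaged 0.154 CPM in WT. It was at 2.94, 3.92 and 0.147 CPM in KO 1 to KO 3, too low for the rule below.

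One hypothesis was that some KO mice carry parts of another strain's genome, so that such genes would lie near one another. Among genes with at least 5 CPM in a library, a range of at least 2 on the log2 scale in KO and at most 1 in WT picked 19. Of these, 4 had another within 2 Mb, Kcnk5 beside Lrmda and Pzp beside Clec1b (random draws averaged 0.989, permutation p 0.0771, one-sided, 10000 draws). Without Lrmda and Clec1b, noticed first, it was 0 of 17 (draws averaged 0.801, permutation p 1), a count too small to decide. The reverse rule in WT picked 34 genes, of which 11 had a neighbour (draws averaged 3.20, permutation p 0.0031), so clusters alone do not show a strain difference between KO mice. This explanation cannot be told apart from a difference in cell state between the libraries, which was not tested.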
